A study of Mus musculus with 14 samples.

How the data were processed

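RNA from 14 mouse samples in 5 groups was measured on one-colour Illumina bead arrays, with 150 ng of total RNA as input, 12 h of in vitro transcription and biotin label, per the labels. The groups were HTF/MultiBlast, ISM1/ISM2, oviduct and micromanipulation control with 3 arrays each, and KSOM(aa) with 2. The series text calls the replicates biological. The 3 micromanipulation control arrays, however, all carry the replicate number 1 in their descriptions, so they may be technical repeats, and p-values measure the spread between the samples as given.

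The deposited intensity values are bead summaries per probe from BeadStudio 3.2, neither background-corrected nor normalized, per the labels. The deposited detection p-values, from BeadStudio 3.2 as well, set each signal against the negative controls of the same array, and the control probes themselves were not used here. The authors' log2 values were background-corrected and quantile-normalized, with lumi and RMA named in the submitters' processing notes without an order. Each column of the authors' values had a median of 2.89 on a scale that orders the probes of an array as the intensities do (rank correlation 1), so its direction is known, while the offset and background step behind its centre are not given in the sources used here. The authors' values served only as an alternative.

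Intensities were background-corrected, quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with negative-control parameters inferred from the detection p-values and an offset of 16. The median was then 4.69 per array. A probe was tested when its detection p was under 0.01 in at least 2 of the 14 samples, which kept 10975 of 25697 probes. Of all probes, 23978 had 1 gene symbol and 1719 had none. Gene IDs of 23962 of them were in the RefSeq table of assembly GRCm38.p6, 16 were not, and 0 symbols changed through the gene ID. Each symbol was represented by its probe with the highest mean over the 14 samples, giving 8669 units, 8025 with a symbol and 644 without. Of the tested symbols, 1801 had more than 1 tested probe. *H19* had no probe, and *Peg3* was detected on 0 arrays.

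A linear model over the 5 groups with empirical Bayes variances (limma, 9 residual and 4.32 prior degrees of freedom) gave 11 comparisons, 4 of them against oviduct as the main ones and 7 second-line, and an F test across groups. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the units of a comparison with a threshold of 0.05. The median SE of a log2 difference was 0.256, and 0.286 with KSOM(aa). Where a gene's probe was not detected on any array of a group, its fold is given as "at least", computed from the brighter group's mean over all its replicates against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own. Arrays were also compared as wholes by the share of squared distance between groups, with a permutation test of 100000 resamples whose smallest possible p is 1e-05. Single pairs of groups cannot go below 0.1 in such a test.

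Named genes were chosen by a rule fixed before the data were examined, as were the gene lists, comparisons and most alternatives. In each main comparison the rule takes the 8 largest rises and 8 largest falls among passing units with a symbol whose arrays did not overlap between the groups. It adds up to 4 members with the smallest p of each of at most 5 called lists. Second-line comparisons take 4 and 4, and up to 2 members of at most 4 lists. Where no unit passed, the 3 with the smallest p in each direction are named as not passing. *Pou5f1*, *Nanog*, *Cdx2*, *Gata3*, *Gata6*, *Sox17*, *Igf2*, *Mest*, *Cdkn1c* and *Grb10* were followed by name. Some genes of the closing section lie outside the rule and are marked there as chosen after their values were seen. *Ovgp1* and the other cell markers were looked up for the sample check only.

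Of 30 gene lists, 28 with at least 5 measured genes were tested with camera (limma, preset correlation 0.01), which asks whether a list moves differently from other genes, with p-values adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and 17 of its 76 calls over all comparisons held. These were amino acid response in 4 comparisons (ISM1/ISM2 and the culture mean against oviduct, and ISM1/ISM2 against KSOM(aa) and the control), primitive endoderm in 8, interferon in 2 (ISM1/ISM2 and the culture mean against oviduct), imprinted genes in 2 and epiblast genes in 1. The fry test (limma with statmod 1.5.0), which asks whether a list's genes move on balance one way, or with its mixed p in either direction, without comparing them with other genes, called 110. Lists of blood and immune cells and of cumulus and granulosa cells had 4 measured genes each and were not tested. With members dark in a group set to their bound, list medians moved by at most 0.51 log2.

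The steps were tested on simulated data of this size, with changed genes among 8669. For HTF/MultiBlast against oviduct, 2 of 67 genes changed by 1.5-fold were recovered, 19 of 67 by 2-fold and 59 of 66 by 4-fold. Of 85 calls, 5 were unchanged genes. For KSOM(aa) against oviduct, 1 of 67, 14 of 67 and 57 of 66 were recovered, with 8 unchanged among 80 calls. Real power may be lower and false calls higher here, as both groups varied most. The overlap of calls between comparisons that share oviduct was set against 100 simulations with the same shared arrays and no change.

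The alternatives were the authors' values, no background correction, scaling to the 75th percentile, an offset of 50, no filter, detection on all arrays, each probe on its own, the mean of the probes, only the groups of a comparison, array weights, a replicate block, a fold of at least 1.5, an adjusted p under 0.01 and each array left out in turn. Oviduct replicate 2 alone, and the control arrays averaged to 1 sample, were added after the data were seen. No array was left out of the main values.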

Results

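Transcript levels in mouse samples of 5 groups were measured on 14 one-colour Illumina bead arrays with 25697 probes each. HTF/MultiBlast (3 arrays) held samples titled MultiBlast/HTF. ISM1/ISM2 (3 arrays) held blastocysts grown in ISM1 and ISM2 media, and KSOM(aa) (2 arrays) held blastocysts grown in KSOM(aa) medium. The other groups were oviduct (3 arrays) and micromanipulation control (3 arrays). The labels leave open whether MultiBlast is a medium or a kind of embryo, so these may not be separable for HTF/MultiBlast. The study's title concerns sperm injection, embryo culture and blastocyst abnormalities, and oviduct served as the common reference. Median intensity ran from 96.6 on oviduct replicate 1 to 152 on oviduct replicate 2, and detected probes from 8533 (33.2% of all) to 10188 (39.6%) on the same arrays. The number of arrays limits the precision of every value.

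The oviduct group carried blastocyst transcripts, as the other groups did. *Cdx2*, a trophectoderm regulator, had a mean log2 intensity of 12.92 ± 0.06 (SD, n = 3) in oviduct and of 12.36 to 13.04 in the other groups. *Nanog*, an epiblast regulator, had 10.98 ± 0.18 (SD, n = 3) in oviduct and 11.79 to 12.04 in the others. *Ovgp1*, the oviduct glycoprotein, and *Pax8*, *Krt5*, *Tppp3*, *Myh11*, *Dcn*, *Ptprc*, *Hba-a1* and *Has2*, markers of epithelium, muscle, stroma, blood and cumulus cells, were detected on 0 of the 14 arrays. *Wfdc2* and *Elf3*, genes of epithelia, were detected on all 14, at means of 12.46 and 11.75 in oviduct and of 12.65 to 12.93 and 11.28 to 12.24 in the others. *Acta2*, a smooth muscle actin, was detected on 2 of 3 oviduct arrays and on 3 of the 11 others, with a mean of 5.16 in oviduct and 5.10 to 5.31 in the others. The cell type label, oviduct, may mean tissue or embryos that grew there. The undetected markers and blastocyst transcripts argue against tissue. Of the markers looked up, *S100a9*, a calcium-binding protein of myeloid cells, was higher in oviduct, at 6.69 ± 0.39 (SD, n = 3). In the other groups it lay near or at background.

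Expression differed between groups, and ISM1/ISM2 lay farthest from oviduct. Groups accounted for 57.8% of the squared distance between arrays, against a mean of 30.8% over permuted labels (permutation test over the 14 arrays, 100000 resamples, p = 5e-05). By pair, the share for KSOM(aa) was 24.8% with oviduct, 25% with the control and 30.4% with HTF/MultiBlast, against 25% by chance (permutation test, 10 splits, p = 0.6, 0.4 and 0.4). The other pairs had the smallest possible p, 0.1, so no pair could pass. The root mean square difference of group means was 0.840 log2 between oviduct and ISM1/ISM2, 0.577 between oviduct and HTF/MultiBlast, 0.489 between oviduct and micromanipulation control, 0.479 between oviduct and KSOM(aa) and 0.557 between HTF/MultiBlast and ISM1/ISM2. KSOM(aa) and micromanipulation control lay closest, at 0.354. The within-group SD, as a root mean square over units, was 0.572 log2 in KSOM(aa), 0.504 in oviduct, 0.377 in ISM1/ISM2, 0.298 in HTF/MultiBlast and 0.249 in micromanipulation control. Of 8669 tested units (a gene, or a probe with no symbol), 1605 (18.5%) differed between groups in limma's F test at an adjusted p under 0.05, and 2982 had an unadjusted p under 0.05. The 1605 became 979 without ISM1/ISM2 replicate 1 and 1049 without ISM1/ISM2 replicate 2.

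**Figure D1:**
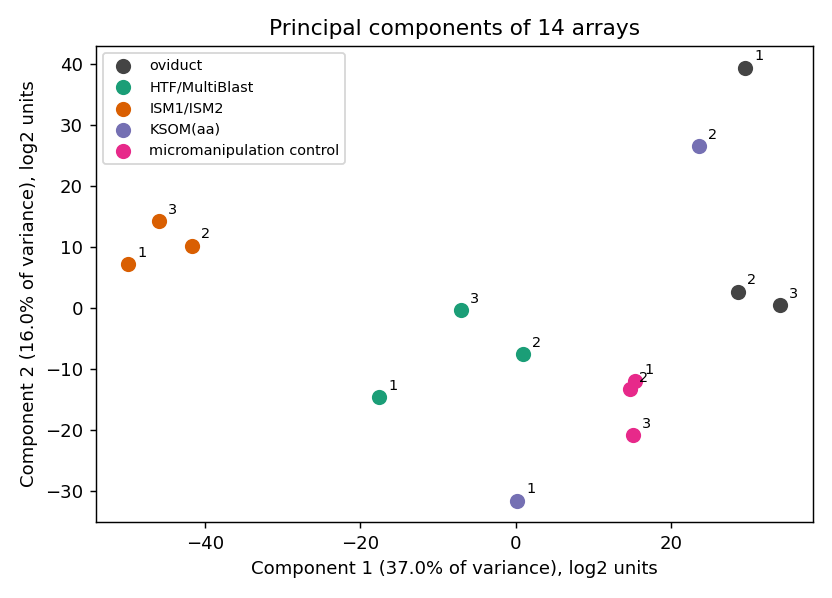
Each point is an array, numbered by replicate, coloured by group and placed by its scores on the first 2 principal components of normalized log2 intensity (37.0% and 16% of the variance). The 3 ISM1/ISM2 arrays lie at -49.9 to -41.7 on the first component and the 3 oviduct arrays at 28.6 to 34.1, while the KSOM(aa) arrays lie far apart, at -31.6 and 26.5 on the second.

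**Figure D2:**
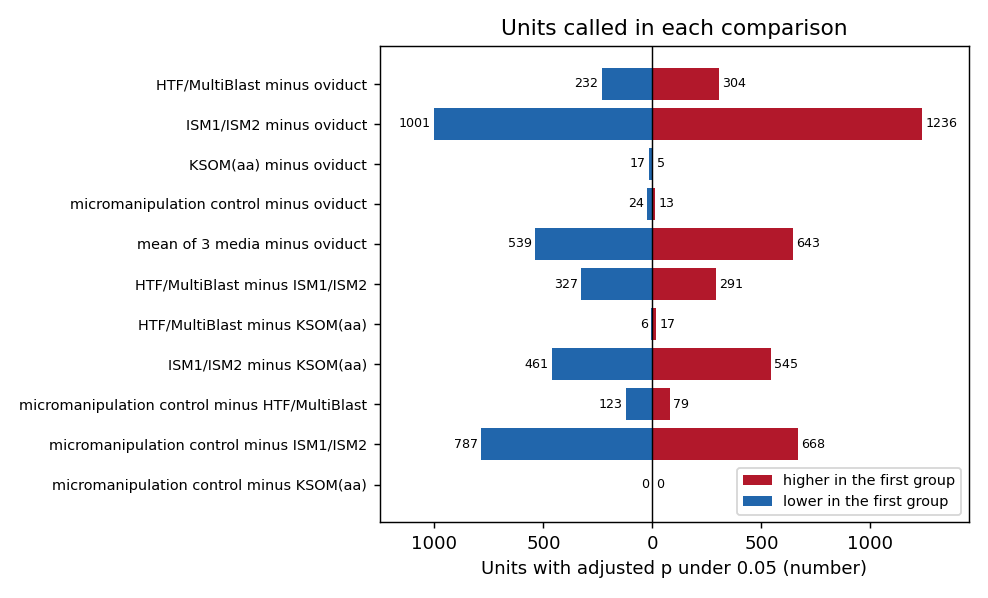
Bars show, for each comparison, the number of units with an adjusted p under 0.05 that were higher (right, red) or lower (left, blue) in the first-named group. ISM1/ISM2 against oviduct has 1236 higher and 1001 lower, and KSOM(aa) against oviduct 5 and 17.

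HTF/MultiBlast samples had less transcript of the primitive endoderm, the lineage that lines the blastocyst cavity, than oviduct. Genes of the amino acid response, which the factor ATF4 switches on when amino acids run short, were also lower (adjusted p = 0.0597 with an estimated correlation). The interferon response list had a higher median with 2 of 8 genes passing, and its call ended likewise (adjusted p = 0.051 with an estimated correlation). Genes of the trophectoderm, the outer lineage, moved little.

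Among single genes, the largest rises in HTF/MultiBlast were of *Nat2*, an arylamine acetyltransferase, *Gpha2*, a glycoprotein hormone subunit, and *Gm773*. *Nat2* rose by 3.06 ± 0.36 log2 (SE, 3 arrays per group here and below; limma adjusted p = 0.000576), *Gpha2* by 3.05 ± 0.59 (adjusted p = 0.00955) and *Gm773* by 2.96 ± 0.63 (adjusted p = 0.0153; 0.0845 without HTF/MultiBlast replicate 1 and 0.0573 without replicate 3). The germline antigen genes *Magea2* and *Magea5*, whose sequences are close enough for probes to cross-react, rose by 2.85 ± 0.43 and 2.73 ± 0.42 (adjusted p = 0.0019 and 0.00251). *Gm16367* rose by 2.83 ± 0.32 and *Bhmt*, which remethylates homocysteine with betaine, by 2.58 ± 0.31 (adjusted p = 0.000477 and 0.000615). *Pxylp1* was at least 3.88-fold higher (adjusted p = 0.00741). The falls were led by *Stc2*, a secreted stress protein, which fell by 2.94 ± 0.44, and *Nupr1*, a stress-induced nuclear protein, which fell by 2.93 ± 0.36 (adjusted p = 0.00188 and 0.000673). *Slc7a3*, an importer of arginine and lysine, fell by 2.81 ± 0.28, *Srgn* (serglycin) by 2.76 ± 0.24 and *Slc7a8*, a neutral amino acid exchanger, by 2.41 ± 0.26 (adjusted p = 0.000237, 0.000182 and 0.000305). *Ctsll3*, a cathepsin L-like protease, fell by 2.63 ± 0.52 (adjusted p = 0.0106). The homeobox gene *Msx1* was at least 5.82-fold lower and the sodium channel subunit *Scnn1b* at least 3.04-fold lower (adjusted p = 0.000241 and 0.000615). Each named gene called between 2 groups had all arrays of the higher group above all of the lower. The naming rule asked this of the largest changes, and 10% of 3-against-3 splits give it by chance. *Gpha2* and *Gm773* were detected on 2 of 3 oviduct arrays and *Srgn* on 1 of 3 HTF/MultiBlast arrays, which limits the precision of their sizes. Other probes gave 1.87 for *Gm773*, 1.33 for *Gm16367*, 0.98 for *Magea5* and -0.76 for *Srgn*.

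In all, 536 units passed between HTF/MultiBlast and oviduct, 304 higher and 232 lower, 383 of them by at least 2-fold, and 1968 had an unadjusted p under 0.05. The count became 175 without HTF/MultiBlast replicate 1, 348 without replicate 2 and 221 without replicate 3, and 824 without KSOM(aa) replicate 2. With replicate 2 as the only oviduct array it became 105, and *Gm773*, *Pxylp1*, *Ctsll3* and *Magea5* no longer passed (adjusted p = 0.199, 0.148, 0.0982 and 0.0531). With the authors' values, *Gm773* and *Ctsll3* did not pass (0.056 and 0.0611). Of 36 measured amino acid response genes, 16 were lower and 0 higher (adjusted over the list alone, 23 and 0), with a median log2 difference of -0.95 (camera adjusted p = 9.69e-19; adjusted p = 0.0597 with an estimated correlation). *Cebpb*, a factor that pairs with ATF4, detected on 2 of 3 HTF/MultiBlast arrays, fell by 1.85 ± 0.24 (adjusted p = 0.00078). Of 17 primitive endoderm genes, 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with a median of -0.95 (adjusted p = 2.5e-08; 0.00317 with an estimated correlation). They included *Amn*, a partner of the cubilin uptake receptor, which fell by 2.30 ± 0.27, *Sox7*, which fell by 2.04 ± 0.24, and *Serpinh1*, a collagen chaperone, which fell by 1.45 ± 0.21 (adjusted p = 0.000576, 0.000615 and 0.00156). Of 8 interferon genes, 2 were higher and 0 lower (5 and 0 adjusted over the list alone), with a median of 0.89 (adjusted p = 0.00155; adjusted p = 0.051 with an estimated correlation; 0.0649 after scaling to the 75th percentile and 0.13 when undetected probes were kept). *Oasl2*, an antiviral gene dark in oviduct, was at least 2.07-fold higher (adjusted p = 0.000685), and *B2m*, the light chain of class I MHC, rose by 1.25 ± 0.34 (adjusted p = 0.0481, at 0.05 or above without any 1 of 11 arrays, all but KSOM(aa) replicates 1 and 2 and oviduct replicate 1, and up to 0.202 without HTF/MultiBlast replicate 1). *Bst2* and *Psmb9* were higher by 0.94 and 0.84 without passing (adjusted p = 0.0769 and 0.0968).

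Trophectoderm and ribosomal protein genes shifted by less, and their calls were the weaker ones. Of 28 trophectoderm genes, 1 was lower and 0 higher (0 and 0 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0255; adjusted p = 0.529 with an estimated correlation). That call ended without HTF/MultiBlast replicate 1 (0.0856) or oviduct replicate 3 (0.0813), and after scaling to the 75th percentile (0.277). The water channel *Aqp8* fell by 0.95 ± 0.26 (adjusted p = 0.0447, up to 0.17 without HTF/MultiBlast replicate 1, and at 0.05 or above without any 1 of 11 arrays, all but both KSOM(aa) arrays and ISM1/ISM2 replicate 1). *Krt7*, a keratin of simple epithelia, was lower by 0.82 without passing (adjusted p = 0.063). Of 56 ribosomal protein genes, 3 were lower and 0 higher (0 and 0 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.0207; adjusted p = 0.529 with an estimated correlation). That call ended without HTF/MultiBlast replicate 2 (0.176) or oviduct replicate 1 (0.187), and after scaling to the 75th percentile (0.139). *Rpl14* fell by 0.87, *Rps12* by 0.59 and *Rps13* by 0.65 (adjusted p = 0.0379, 0.0388 and 0.0498). Each passed in few of the fits with 1 array left out, with adjusted p up to 0.176 (*Rps13*, without HTF/MultiBlast replicate 1).

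Of the lineage and imprinted genes fixed by name, *Nanog* rose in HTF/MultiBlast by 0.81 ± 0.21 (adjusted p = 0.0411) and *Gata6*, a primitive endoderm factor, by 0.80 ± 0.18 (adjusted p = 0.0223). *Cdkn1c*, a maternally expressed inhibitor of the cell cycle, rose by 1.85 ± 0.41 (adjusted p = 0.019), and *Grb10*, an imprinted adaptor of insulin signalling, fell by 1.64 ± 0.37 (adjusted p = 0.0216). None of these calls held without HTF/MultiBlast replicate 1 (adjusted p = 0.168 for *Nanog*, 0.112 for *Gata6*, 0.0863 for *Cdkn1c* and 0.0964 for *Grb10*). The *Nanog* call also ended without HTF/MultiBlast replicate 2, ISM1/ISM2 replicate 1 or 2, oviduct replicate 1 or 3, or any 1 control array. It ended with the authors' values (0.0539), with undetected probes kept (0.0543), with array weights (0.0744), with a replicate block (0.0598) and with only the 2 groups in the fit (0.109). The *Gata6* call also ended without HTF/MultiBlast replicate 2 or oviduct replicate 3 and with only the 2 groups in the fit (0.0864), the *Cdkn1c* call without HTF/MultiBlast replicate 3 and with undetected probes kept (0.0586), and the *Grb10* call without HTF/MultiBlast replicate 3 or oviduct replicate 2 or 3, with undetected probes kept (0.0606) and after scaling to the 75th percentile (0.0674). With replicate 2 as the only oviduct array, none of the 4 passed (0.465 for *Nanog*, 0.191 for *Gata6*, 0.205 for *Cdkn1c* and 0.0577 for *Grb10*). *Pou5f1* differed by -0.40, *Cdx2* by -0.24, *Gata3* by -0.09, *Sox17* by 0.09 (-0.55 on its other probe), *Igf2* by 0.48 and *Mest* by 0.98 (0.57 on another probe), none passing.

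ISM1/ISM2 samples differed widely from oviduct. The amino acid response and primitive endoderm genes were lower here too, with some members dark, and interferon genes were higher. Genes of the epiblast and pluripotency list were lower as a group, a call that ended with probes detected on all arrays only (adjusted p = 0.0852). The list did not move as one, since *Nanog* was higher and *Pou5f1* did not pass. Trophectoderm genes were lower (adjusted p = 0.0941 with an estimated correlation). Genes of cholesterol synthesis, oxidative stress and other lists also moved, and those calls ended in the same way.

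*Slc7a3* fell below detection in ISM1/ISM2, at least 73.6-fold lower than in oviduct (limma adjusted p = 2.61e-08). *Ctsll3* fell to background, where 1 of 3 ISM1/ISM2 arrays detected it, by 7.37 ± 0.52 log2 (adjusted p = 1.27e-06), or -7.00 with signals under the lowest detected one raised to it ("at the floor" below), and *Nupr1* and the muscle LIM protein gene *Fhl1* were at least 29.1-fold and at least 15.1-fold lower. The glutathione-degrading enzyme *Chac1* fell by 5.66 ± 0.38, the ATF4-related factor *Atf5* by 4.37 ± 0.49, the neutral amino acid transporter *Slc1a4* by 4.19 ± 0.28 and *BC051665* by 4.42 ± 0.47. *Oasl2* and *Actn2*, a muscle actinin, were at least 10.6-fold and at least 11.5-fold higher (adjusted p = 4.81e-07 and 7.61e-07). *Gm16367* rose by 3.85 ± 0.32, *Gulo*, which makes vitamin C, by 3.84 ± 0.43, and *Pemt*, which makes phosphatidylcholine by methylation, by 3.80 ± 0.43. *Ly96*, the partner of a bacterial lipid receptor, rose by 3.79 ± 0.89 (adjusted p = 0.00739), *Tns4*, an adhesion protein, by 3.72 ± 0.36 and *Mocos*, which activates molybdenum enzymes, by 3.33 ± 0.52. *Chac1* and *Slc1a4* were detected on 2 of 3 ISM1/ISM2 arrays, *Gulo*, *Ly96* and *Mocos* on 2 of 3 oviduct arrays and *Tns4* on 1 (3.27 at the floor), and another probe of *Gm16367* gave 2.08. A total of 2237 units passed, 1236 higher and 1001 lower, 1330 of them by at least 2-fold, with 3289 at an unadjusted p under 0.05. With replicate 2 as the only oviduct array, 1170 passed.

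Of the 36 amino acid response genes, 32 were lower in ISM1/ISM2 and 0 higher (the same adjusted over the list alone), with a median of -1.55 (camera adjusted p = 3.02e-23; 0.0478 with an estimated correlation). *Asns*, which makes asparagine, fell by 2.54 ± 0.16 (adjusted p = 7.61e-07; -1.13 on another probe). Of the 17 primitive endoderm genes, 13 were lower and 1 higher (the same adjusted over the list alone), with a median of -2.41 (adjusted p = 4.47e-11; 0.00102 with an estimated correlation). The basement membrane genes *Lama1* and *Lamb1* fell by 4.18 ± 0.24 and 2.82 ± 0.24, and *Srgn* (-0.74 log2 on another probe) and *Serpinh1* were at least 6.4-fold and at least 7.67-fold lower. Of the 28 trophectoderm genes, 14 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -0.80 (adjusted p = 3.15e-07; adjusted p = 0.0941 with an estimated correlation). Among them *Elf5* and *Eomes*, factors that keep trophoblast stem cells, changed by -3.75 ± 0.37 and -1.99 ± 0.20, *Aqp8* by -2.69 ± 0.26 and *Ets2* by -1.79 ± 0.23. Of the 22 epiblast and pluripotency genes, 11 were lower and 4 higher (13 and 4 adjusted over the list alone), with a median of -0.80 (adjusted p = 0.0053; 0.0493 with an estimated correlation; 0.0852 with probes detected on all arrays only). Of 16 genes of the unfolded protein response, 5 were lower and 0 higher (8 and 1 adjusted over the list alone), with a median of -0.70 (adjusted p = 0.0053; adjusted p = 0.118 with an estimated correlation). *Herpud1*, which helps degrade misfolded proteins, fell by 2.93 ± 0.21, *Xbp1*, a factor that drives the response, by 1.21, and *Syvn1* and *Hsp90b1* by 0.92 and 0.82.

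The 8 interferon genes had 4 higher and 0 lower in ISM1/ISM2 (the same adjusted over the list alone), with a median of 0.94 (camera adjusted p = 0.0053; 0.0493 with an estimated correlation). *B2m* rose by 2.68 ± 0.34 (adjusted p = 0.000112), *Bst2* by 1.38 and *Psmb9* by 1.33. The interferon call ended when undetected probes were kept in the test (0.15). The calls of the other higher lists ended with an estimated correlation. p53 targets had 7 of 21 higher and 0 lower, a median of 0.36 and adjusted p = 0.0125 (adjusted p = 0.147 with an estimated correlation). Cholesterol genes had 6 of 17 higher and 0 lower, a median of 0.65 and adjusted p = 0.0232 (adjusted p = 0.379 with an estimated correlation; 0.109 without ISM1/ISM2 replicate 1 and 0.0512 without oviduct replicate 1). Oocyte transcripts had 3 of 7 higher and 0 lower (5 and 0 adjusted over the list alone), a median of 1.48 and adjusted p = 0.0284 (adjusted p = 0.1 with an estimated correlation). NRF2 targets, the genes of the oxidative stress response, had 7 of 23 higher and 0 lower, a median of 0.34 and adjusted p = 0.0302 (adjusted p = 0.358 with an estimated correlation). The NRF2 call ended without ISM1/ISM2 replicate 3, oviduct replicate 2 (0.094) or oviduct replicate 3 (0.101). Lysosome genes had 10 of 27 higher and 2 lower, a median of 0.28 and adjusted p = 0.0471 (adjusted p = 0.118 with an estimated correlation). The lysosome call ended with a replicate block (0.0536) and without any 1 HTF/MultiBlast or oviduct array or ISM1/ISM2 replicate 3, with adjusted p up to 0.0733 (oviduct replicate 3). Sex-linked genes had 4 of 7 higher and 0 lower, a median of 0.87 and adjusted p = 0.0302 (adjusted p = 0.226 with an estimated correlation; 0.0623 without ISM1/ISM2 replicate 3, 0.0972 without oviduct replicate 1 and 0.0804 after scaling to the 75th percentile). Regulators of DNA methylation and chromatin had 8 of 29 lower and 0 higher (8 and 1 adjusted over the list alone), a median of -0.25 and adjusted p = 0.0302 (adjusted p = 0.0941 with an estimated correlation; 0.0534 without oviduct replicate 3; 0.125 after scaling to the 75th percentile).

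Among the fixed genes, *Nanog* rose in ISM1/ISM2 by 1.07 (adjusted p = 0.00279), *Cdkn1c* by 2.13 (0.00212) and *Mest*, a paternally expressed hydrolase detected on 2 of 3 oviduct arrays, by 1.69 (0.00821). *Grb10* fell by 3.35 (adjusted p = 3.92e-05), *Sox17*, an endoderm factor, by 1.48 (0.00594) and the growth factor *Igf2* by 1.33 (0.00187). *Gata6* rose by 0.58 (adjusted p = 0.0323), a call that ended without ISM1/ISM2 replicate 1 (0.112), ISM1/ISM2 replicate 3, oviduct replicate 2 or oviduct replicate 3. *Gata3*, a trophectoderm factor, fell by 0.68 (adjusted p = 0.036), a call that ended without ISM1/ISM2 replicate 1 (0.153), ISM1/ISM2 replicate 2, oviduct replicate 2 or 3, or micromanipulation control replicate 1. *Pou5f1* differed by -0.02 and *Cdx2* by -0.56 (adjusted p = 0.139), neither passing.

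**Figure D3:**
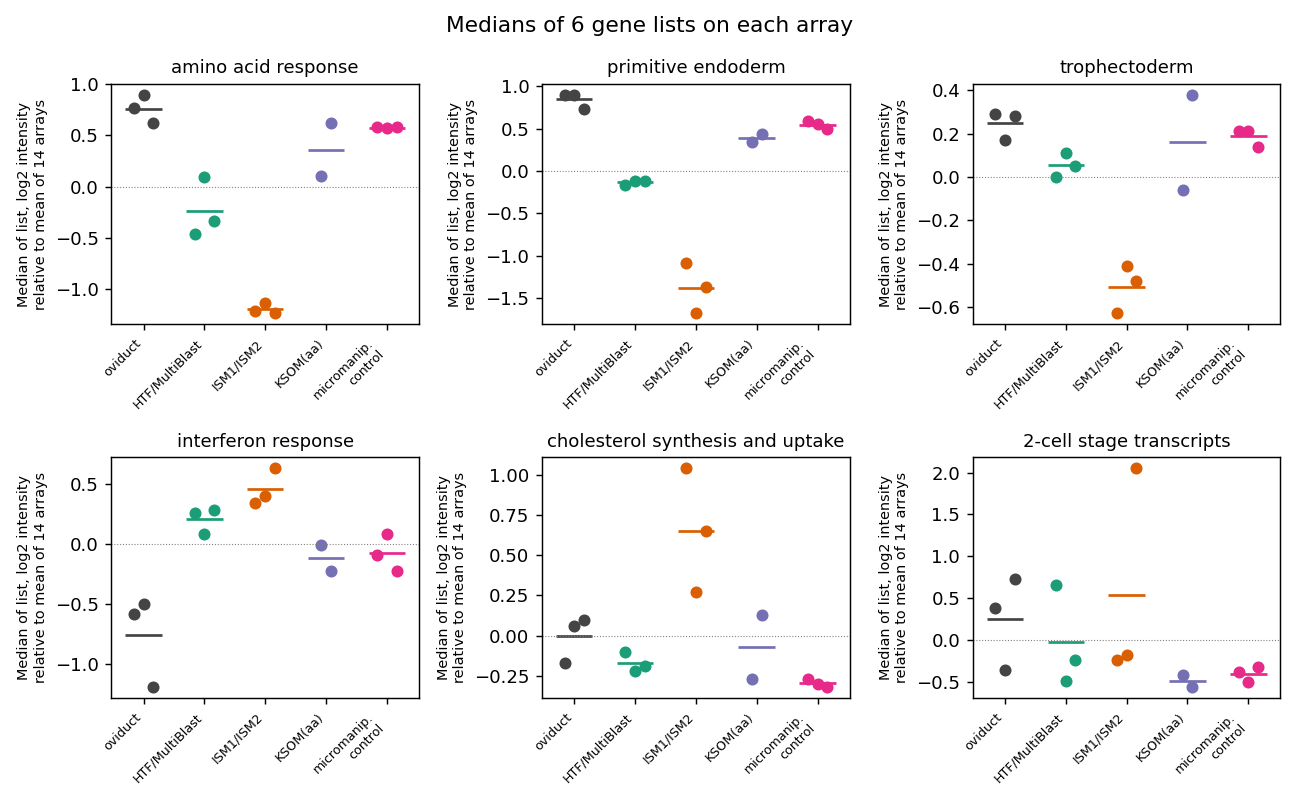
Points give, for each array, the median over the genes of a list of log2 intensity relative to the gene's mean over the 14 arrays, with a line at each group's mean of its arrays, for 6 lists. Amino acid response medians lie at -1.24 to -1.14 on the ISM1/ISM2 arrays and 0.62 to 0.90 on the oviduct arrays.

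Few genes passed between KSOM(aa) and oviduct, in a comparison with 2 KSOM(aa) arrays and low power. The homeobox genes *Hoxc6* and *Msx1* went opposite ways. *Crym*, which binds thyroid hormone, and *Trh*, the thyrotropin-releasing hormone, were both lower. *Phlda2*, an imprinted gene that restrains placental growth, was lower as well.

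In KSOM(aa), *Hoxc6*, detected on 1 of 3 oviduct arrays, rose by 2.23 ± 0.30 log2 (SE, 2 arrays against 3; limma adjusted p = 0.00922), or 1.60 at the floor, and *Crym* fell by 2.40 ± 0.27 (0.00559). *Msx1* was at least 5.61-fold and *Scnn1b* at least 2.92-fold lower (adjusted p = 0.00733 and 0.00922), and *Fam25c* fell by 2.08 (0.0214). These 5 genes passed with each array left out in turn. *Ctsll3* fell by 3.55 ± 0.58 and *1300017J02Rik* rose by 2.03 ± 0.32 (adjusted p = 0.0279 each), with adjusted p of 0.097 and 0.0697 without oviduct replicate 3. *Trh* fell by 1.92 (adjusted p = 0.029; 0.126 without KSOM(aa) replicate 1 and 0.0532 without HTF/MultiBlast replicate 3). *Phlda2* fell by 1.79 ± 0.32 (adjusted p = 0.0415) and *Pfkp*, a phosphofructokinase detected on 1 of 2 KSOM(aa) arrays, by 1.64 (0.0422; -1.14 at the floor and -0.24 on another probe). *Dck*, a deoxynucleoside kinase detected on 1 of 3 oviduct arrays, rose by 1.77 (1.44 at the floor), and *Clec10a*, a lectin, by 1.76, while *Tulp1* was at least 2.80-fold lower (adjusted p = 0.0376, 0.0415 and 0.0378). The calls of *Phlda2*, *Pfkp*, *Clec10a* and *Tulp1* ended without most single arrays, with adjusted p up to 0.162, 0.12 and 0.114 for *Phlda2*, *Pfkp* and *Tulp1* without KSOM(aa) replicate 1 and 0.118 for *Clec10a* without oviduct replicate 3. The *Dck* call ended without HTF/MultiBlast replicate 2 or 3, ISM1/ISM2 replicate 2, oviduct replicate 3 (0.11) or micromanipulation control replicate 2.

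The count for KSOM(aa) against oviduct was 22 units, 5 higher and 17 lower, all 22 by at least 2-fold, with 1086 at an unadjusted p under 0.05. It ranged from 6 without oviduct replicate 3 to 286 without KSOM(aa) replicate 2 over the arrays left out. With the arrays of these 2 groups alone in limma, 0 units passed and 397 had an unadjusted p under 0.05. Of the amino acid response genes, 0 passed in either direction (1 lower adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.000208; adjusted p = 0.561 with an estimated correlation; 0.41 without KSOM(aa) replicate 1, where the median was -0.09). Of 15 glycolysis genes, 1 was lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0106; adjusted p = 0.365 with an estimated correlation; 0.36 without KSOM(aa) replicate 1, with a median of -0.12, and 0.0552 without oviduct replicate 1). *Pkm*, *Slc2a1* and *Ldha*, a kinase, a glucose transporter and a dehydrogenase of that path, were lower by 1.01, 1.04 and 0.91 without passing. Of the ribosomal protein genes, 0 passed, with a median of -0.11 (adjusted p = 0.0191; adjusted p = 0.611 with an estimated correlation; 0.899 without KSOM(aa) replicate 2, with a median of -0.01, and 0.184 without oviduct replicate 1). Of the primitive endoderm genes, 0 passed (2 lower and 1 higher adjusted over the list alone), with a median of -0.33 (adjusted p = 0.03; adjusted p = 0.365 with an estimated correlation). The primitive endoderm call ended without KSOM(aa) replicate 1 (0.36), KSOM(aa) replicate 2 (0.101), or oviduct replicate 1 or 2, and after scaling to the 75th percentile (0.308), which also ended the ribosomal call (0.526). *Stc2* and *Slc7a3* were lower by 2.06 and 1.10, and *Gata6* and *Nanog* higher by 0.92 and 0.86, none passing (adjusted p = 0.126, 0.175, 0.1 and 0.16).

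Few genes passed between the micromanipulation control and oviduct. *Phlda2* and the signalling ligand *Bmp4* were lower. *Hoxc6*, *Crym*, *Msx1*, *Ctsll3* and *1300017J02Rik* were called in the same direction as in KSOM(aa). No gene list was called, and the amino acid response and primitive endoderm genes had medians near 0.

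In the micromanipulation control, *Phlda2* fell by 2.99 ± 0.29 log2 (SE, 3 arrays per group; limma adjusted p = 0.000766), the call that passed with each array left out in turn. *Crym* fell by 2.03 ± 0.24 and *Tpm2*, a tropomyosin, by 1.92 (adjusted p = 0.0051 and 0.00861), with an adjusted p of 0.0519 for each without micromanipulation control replicate 1. *Ctsll3* fell by 3.06 ± 0.52, *Bmp4* by 2.20 ± 0.35 and *Msx1* by 1.93 (adjusted p = 0.0193, 0.0154 and 0.0146). *Tulp1* and *Pfkp* were at least 2.71-fold and at least 2.55-fold lower (adjusted p = 0.0192 and 0.0122), with -0.44 log2 on another probe of *Pfkp*. *Zfp943* rose by 2.82 ± 0.51 (adjusted p = 0.0289) and *Upk1b*, a uroplakin, by 2.32 ± 0.35 (0.0146). *1300017J02Rik* rose by 1.89, *Hoxc6* by 1.83 (1.21 at the floor), *Kcnv2* by 1.56 (1.16 at the floor), *Tmem131l* by 1.52, *Ndrg4* by 1.45 and *Ak3* by 1.44 (0.62 on another probe). *Hoxc6* and *Kcnv2* were detected on 1 and *Zfp943* and *Tmem131l* on 2 of 3 oviduct arrays, and *Msx1* on 2 of 3 control arrays. Each of these genes except *Phlda2* lost its call without at least 1 micromanipulation control array, with adjusted p up to 0.179 (*Kcnv2*, without replicate 2).

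The count for micromanipulation control against oviduct was 37 units, 13 higher and 24 lower, 35 of them by at least 2-fold, with 1476 at an unadjusted p under 0.05. It became 1, 5 and 9 without control replicates 1, 2 and 3, and 176 without KSOM(aa) replicate 1. With the control arrays averaged to 1 sample, 0 units passed in limma and 357 had an unadjusted p under 0.05. By camera, 0 of 28 lists were called, the smallest adjusted p being 0.0551. The epiblast genes had a median of -0.27 with 0 higher and 1 lower (1 and 2 adjusted over the list alone), and the amino acid response genes a median of -0.12 (adjusted p = 0.136). Primitive endoderm and trophectoderm genes had medians of -0.16 and -0.03 (adjusted p = 0.382 and 0.287). *Gata6* and *Nanog* were higher by 0.91 and 0.86 without passing (adjusted p = 0.0511 and 0.0959).

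The mean of the 3 culture groups against oviduct asks how these groups differed from oviduct on average. Amino acid response and primitive endoderm genes were lower, and interferon genes were higher. *Slc7a3* fell by 3.54 ± 0.24 log2 (8 culture arrays against 3; limma adjusted p = 9.17e-06; -3.37 at the floor), *Ctsll3* by 4.52 ± 0.43, *Nupr1* fell by 3.16 (-2.93 at the floor), *Stc2* fell by 2.98 (-2.81), *Srgn* fell by 2.32 (-2.01), *Grb10* fell by 2.18 and *Lama1* by 2.11, and *Msx1* was at least 5.60-fold lower. *Gm16367* rose by 2.66 ± 0.27, *Gulo* by 2.65, *Zfp943* by 2.63, *Sycn* by 2.61, *Nanog* by 0.91 and *Gata6* by 0.77. *Slc7a3*, *Nupr1*, *Stc2* and *Srgn* were detected on 0 of 3 ISM1/ISM2 arrays, *Gulo*, *Zfp943*, *Sycn* and *Mest* were detected on 2 of 3 oviduct arrays, and other probes gave 1.11 for *Gm16367*, -0.51 for *Srgn* and 0.77 for *Mest*. *Oasl2* was at least 2.28-fold higher and *B2m* rose by 1.65, while *Aqp8* fell by 1.37 and *Eomes* by 0.96. *Mest* rose by 1.33 (adjusted p = 0.0948 without oviduct replicate 3) and *Cdkn1c* by 1.32 (0.105 without oviduct replicate 1). For *Nupr1*, *Aqp8*, *Eomes*, *Oasl2*, *B2m*, *Mest* and *Cdkn1c*, the culture arrays and the oviduct arrays overlapped. A total of 1182 units passed, 643 higher and 539 lower, 551 of them by at least 2-fold, with 2553 at an unadjusted p under 0.05. It became 689 without oviduct replicate 3 and 1881 without KSOM(aa) replicate 2.

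By list, the amino acid response had 19 genes lower and 0 higher in the culture mean (29 and 0 adjusted over the list alone), with a median of -0.96 (camera adjusted p = 2.98e-21; 0.0416 with an estimated correlation). Primitive endoderm had 11 lower and 1 higher (the same adjusted over the list alone), with a median of -1.37 (adjusted p = 1.12e-09; 0.00175 with an estimated correlation). Interferon had 4 higher and 0 lower, with a median of 0.82 (adjusted p = 0.00171; 0.0416 with an estimated correlation; 0.0953 when undetected probes were kept). Trophectoderm had 7 lower and 0 higher (9 and 1 adjusted over the list alone), with a median of -0.38 (adjusted p = 5.15e-05; adjusted p = 0.213 with an estimated correlation). Epiblast genes had 7 lower and 3 higher, a median of -0.31 and adjusted p = 0.0283 (adjusted p = 0.102 with an estimated correlation; 0.1 without oviduct replicate 1 and 0.472 with probes detected on all arrays only). The unfolded protein response had 3 lower and 0 higher, a median of -0.47 and adjusted p = 0.0283 (adjusted p = 0.223 with an estimated correlation; 0.0581 without oviduct replicate 2, and also ended without oviduct replicate 3). DNA methylation and chromatin regulators had 4 lower and 0 higher, a median of -0.19 and adjusted p = 0.0406 (adjusted p = 0.106 with an estimated correlation), a call that ended without ISM1/ISM2 replicate 1 or oviduct replicate 1 or 3 (0.0938). Glycolysis genes had 3 lower and 1 higher, a median of -0.29 and adjusted p = 0.0406 (adjusted p = 0.296 with an estimated correlation), a call that ended without ISM1/ISM2 replicate 3, KSOM(aa) replicate 1 or oviduct replicate 1 (0.1) or 2. p53 targets had 5 higher and 0 lower, a median of 0.29 and adjusted p = 0.0406 (adjusted p = 0.291 with an estimated correlation), a call that ended without ISM1/ISM2 replicate 1 or 3, KSOM(aa) replicate 2 or any 1 oviduct array (up to 0.118 without replicate 3).

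Against oviduct, the HTF/MultiBlast and ISM1/ISM2 calls shared 432 units in the same direction, 237 higher and 195 lower. Independent lists of the same sizes would share 43.3 higher and 26.8 lower. Simulations sharing only the oviduct arrays gave a mean of 19.2 and a maximum of 1693. The covariance of the differences was 0.363 (0.0555 simulated). The 432 became 158 without HTF/MultiBlast replicate 1 and 656 without KSOM(aa) replicate 2. KSOM(aa) shared 20 of its 22 calls with ISM1/ISM2, 18 with HTF/MultiBlast and 16 with the control, and the control shared 29 of its 37 with ISM1/ISM2, with 2 more opposite, and 23 with HTF/MultiBlast. Independent lists would share 0.713 higher and 1.96 lower, 0.175 and 0.455, 0.0075 and 0.0471, 1.85 and 2.77, and 0.456 and 0.642. The simulated means were 3.62 (maximum 362), 0, 0.01 (maximum 1), 0 and 0, and covariances of 0.171 to 0.221 stood against 0.0453 to 0.0516. The 16 became 0 without control replicate 1 and 81 without KSOM(aa) replicate 2. Part of each excess may come from the shared oviduct arrays, which cannot be split into sets of at least 2.

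HTF/MultiBlast and ISM1/ISM2 also differed in many genes. Primitive endoderm genes were higher in HTF/MultiBlast. Amino acid response and trophectoderm genes were higher too (adjusted p = 0.124 for each with an estimated correlation). *Slc7a3* was at least 10.5-fold higher in HTF/MultiBlast, and *Ctsll3* rose by 4.74 log2 (4.37 at the floor), *BC051665* by 3.99, *Chac1* by 3.69, *Slc1a4* by 3.02, *Elf5* by 2.81, *Lama1* by 2.51, *Eomes* by 1.62 and *Igf2* by 1.80, while *Serpinh1* was at least 2.81-fold higher. The motor gene *Kif3c*, detected on 1 of 3 HTF/MultiBlast arrays, fell by 2.80 (-2.58 at the floor), *Pemt* by 2.75, the oocyte gene *Padi6* by 2.55, *Ms4a10* by 2.51, the sterol enzyme *Ebp* by 1.89 and *Insig1*, a brake on sterol synthesis, by 1.29 (-1.36 and -0.07 on other probes). *Sox17* and *Grb10* rose by 1.57 and 1.70 (limma adjusted p = 0.0125 and 0.014), with adjusted p of 0.0597 and 0.0651 without HTF/MultiBlast replicate 2. The *Sox17* call also ended without HTF/MultiBlast replicate 1 or ISM1/ISM2 replicate 2, and the *Grb10* call without HTF/MultiBlast replicate 3 or ISM1/ISM2 replicate 3. A total of 618 units passed, 291 higher and 327 lower, 407 of them by at least 2-fold, with 1884 at an unadjusted p under 0.05. The count became 279 and 333 without HTF/MultiBlast replicates 2 and 3, and 312 without ISM1/ISM2 replicate 1.

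Of the amino acid response genes, 12 were higher and 0 lower in HTF/MultiBlast than in ISM1/ISM2 (18 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 5.68e-15; adjusted p = 0.124 with an estimated correlation). Of the primitive endoderm genes, 9 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.79 (adjusted p = 5.55e-09; 0.00236 with an estimated correlation). Trophectoderm had 8 higher and 0 lower (14 and 0 adjusted over the list alone), a median of 0.60 and adjusted p = 1.38e-07 (adjusted p = 0.124 with an estimated correlation). Cholesterol genes had 5 lower and 0 higher (8 and 0 adjusted over the list alone), a median of -0.75 and adjusted p = 8.85e-06 (adjusted p = 0.14 with an estimated correlation). The lower lists included NRF2 targets (median -0.52, adjusted p = 0.000251), oxidative phosphorylation (-0.24, 0.000324), fatty acid synthesis (-0.40, 0.0012), p53 targets (-0.43, 0.00829), ribosomal proteins (-0.18, 0.0166) and oocyte transcripts (-0.70, 0.0173). These had adjusted p = 0.14, 0.264, 0.161, 0.14, 0.385 and 0.124 with an estimated correlation. The unfolded protein response (0.33, 0.016), epiblast (0.37, 0.0166) and osmotic response (0.25, 0.0319) lists were higher, with adjusted p = 0.14, 0.124 and 0.134 with an estimated correlation. The ribosomal call ended without HTF/MultiBlast replicate 2 or ISM1/ISM2 replicate 3 (0.133), the unfolded protein call without ISM1/ISM2 replicate 1 (0.061) or 2, and the osmotic call without HTF/MultiBlast replicate 2 or ISM1/ISM2 replicate 1 or 2 (0.0751).

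HTF/MultiBlast and KSOM(aa) differed in few single genes. The imprinted neighbours *Phlda2* and *Slc22a18* were higher in HTF/MultiBlast, and *Srgn*, *Slc7a3* and the signalling inhibitor *Lefty2* were lower. *Phlda2* rose by 2.37 ± 0.32 log2 (3 arrays against 2; limma adjusted p = 0.00906; 0.0539 without HTF/MultiBlast replicate 3) and *Slc22a18*, a membrane transporter detected on 1 of 2 KSOM(aa) arrays, by 2.14 (0.00514). *Lhfp* was at least 3.06-fold higher (adjusted p = 0.00196), and *Srgn* fell by 2.12 (0.00514; -0.73 on another probe). *Rab38*, a vesicle GTPase, was at least 4.50-fold higher (0.77 log2 on another probe; adjusted p = 0.0129; 0.103 without KSOM(aa) replicate 2, and ended without HTF/MultiBlast replicate 1 or 3). *Nostrin* fell by 1.57 (adjusted p = 0.00906; 0.0557 without HTF/MultiBlast replicate 3). *Nat2* rose by 2.21, *Slc7a3* fell by 1.71 and *Lefty2* was at least 1.81-fold lower (adjusted p = 0.0435, 0.0473 and 0.0424), and each of these 3 calls ended without any 1 of 11 arrays, with adjusted p up to 0.207, 0.211 and 0.177. With the arrays of these 2 groups alone in limma, 0 units passed and 721 had an unadjusted p under 0.05. *Cdkn1c* was higher by 1.86 without passing (adjusted p = 0.148). The count was 23 units, 17 higher and 6 lower, all 23 by at least 2-fold, with 802 at an unadjusted p under 0.05. It ranged from 3 without HTF/MultiBlast replicate 3 to 167 without KSOM(aa) replicate 1 over the arrays left out. The amino acid response list had a median of -0.65, 1 gene lower and 0 higher (4 and 0 adjusted over the list alone) and adjusted p = 1.2e-14 by camera (adjusted p = 0.115 with an estimated correlation). Primitive endoderm had a median of -0.56, 1 lower and 0 higher (5 and 0 adjusted over the list alone) and adjusted p = 2.57e-09 (0.00204 with an estimated correlation). Of 23 imprinted genes, 2 were higher and 0 lower (6 and 1 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.000328; 0.0212 with an estimated correlation; 0.0565 when undetected probes were kept). Oxidative phosphorylation had 0 of 61 genes passing, a median of -0.17 and adjusted p = 0.000328 (adjusted p = 0.719 with an estimated correlation; 0.699 without KSOM(aa) replicate 1, with a median of -0.08).

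ISM1/ISM2 and KSOM(aa) differed widely. Amino acid response and primitive endoderm genes were lower in ISM1/ISM2. *Slc7a3* and *Nupr1* were at least 34.3-fold and at least 14.7-fold lower, *Chac1* fell by 4.80 log2, *BC051665* by 4.16, *Slc1a4* by 3.83, *Lama1* by 3.71, *Elf5* by 3.14, *Aqp8* by 2.23, *Sox17* by 1.94 and *Igf2* by 1.25, and *Serpinh1* was at least 6.09-fold lower. *Oasl2* and *Arg2*, an arginase, were at least 10.9-fold and at least 6.78-fold higher, and *Bhmt2*, detected on 1 of 2 KSOM(aa) arrays, rose by 3.98 (3.43 at the floor), *Actn2* by 3.42 and *Ebp* by 1.95. *Tm7sf2*, a sterol reductase also detected on 1 of 2, rose by 0.81 (0.68 at the floor; limma adjusted p = 0.0158; 0.0698 without KSOM(aa) replicate 1, and ended without ISM1/ISM2 replicate 1). *Cdkn1c* rose by 2.15 (adjusted p = 0.00885; 0.0947 without KSOM(aa) replicate 2) and *Grb10* fell by 1.78 (0.0141; 0.104 without KSOM(aa) replicate 1). A total of 1006 units passed, 545 higher and 461 lower, 708 of them by at least 2-fold, with 2289 at an unadjusted p under 0.05. The count became 598 without ISM1/ISM2 replicate 1 and 627 without KSOM(aa) replicate 2.

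Of the amino acid response genes, 24 were lower and 0 higher in ISM1/ISM2 than in KSOM(aa) (29 and 0 adjusted over the list alone), with a median of -1.72 (camera adjusted p = 5.49e-23; 0.0494 with an estimated correlation). Primitive endoderm had 13 lower and 0 higher (the same adjusted over the list alone), with a median of -1.94 (adjusted p = 1.14e-13; 0.000428 with an estimated correlation), which moved to -1.43 with members dark in a group set to their bound. Trophectoderm had 10 lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -0.58 (adjusted p = 2.35e-06; adjusted p = 0.109 with an estimated correlation). The higher lists were cholesterol (median 0.74, adjusted p = 0.00242), NRF2 targets (0.39, 0.00343), fatty acid synthesis (0.49, 0.00722), 2-cell stage transcripts (0.98, 0.00722), lysosome (0.33, 0.0123), interferon (0.59, 0.022) and oocyte transcripts (0.60, 0.0395). These had adjusted p = 0.29, 0.278, 0.29, 0.384, 0.0954, 0.109 and 0.133 with an estimated correlation. The unfolded protein response (-0.44, 0.00791), epiblast (-0.65, 0.0144) and osmotic response (-0.28, 0.022) lists were lower, with adjusted p = 0.143, 0.0954 and 0.109 with an estimated correlation. The epiblast median moved to -0.31 with members dark in a group set to their bound. The 2-cell call ended without ISM1/ISM2 replicate 3 (0.235), where the median was 0.31, the lysosome and osmotic calls without KSOM(aa) replicate 1 (0.0797 and 0.0696), and the oocyte call without ISM1/ISM2 replicate 1 or 2, KSOM(aa) replicate 1 (0.0797) or 2, or oviduct replicate 1. The interferon call ended when undetected probes were kept (0.506), with a median of -0.02, and the epiblast call with probes detected on all arrays only (0.0615).

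The micromanipulation control carried more primitive endoderm transcript than HTF/MultiBlast. Imprinted genes were lower, led by *Phlda2*. Amino acid response genes were higher (adjusted p = 0.0524 with an estimated correlation). *Phlda2* fell by 3.57 ± 0.29 log2 (limma adjusted p = 8.76e-05), *Bhmt* by 3.26, *Nat2* by 3.00 and *Slc22a18* by 1.91 (0.00107), and *Rab38* was at least 4.35-fold lower (-0.78 log2 on another probe). *Nupr1* rose by 2.97, *Srgn* by 2.65 (0.53 on another probe), *Slc7a3* by 2.25 and *Sox7* by 1.63. *Cox6a2*, a cytochrome oxidase subunit of muscle, was at least 5.10-fold higher (adjusted p = 0.00748; 0.0523 without HTF/MultiBlast replicate 1). *Cdkn1c* fell by 2.16 (adjusted p = 0.0145; 0.0775 without micromanipulation control replicate 3, and ended without replicate 2 or HTF/MultiBlast replicate 1 or 3). A total of 202 units passed, 79 higher and 123 lower, 164 of them by at least 2-fold, with 1197 at an unadjusted p under 0.05. The count became 45 and 70 without HTF/MultiBlast replicates 1 and 3, and 84, 67 and 69 without control replicates 1, 2 and 3. With the control arrays, possible technical repeats, averaged to 1 sample, it became 2. The amino acid response had 8 higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.27e-19; adjusted p = 0.0524 with an estimated correlation). Primitive endoderm had 7 higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.65 (adjusted p = 2.45e-11; 0.000925 with an estimated correlation). Imprinted genes had 4 lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.000771; 0.0266 with an estimated correlation). Oxidative phosphorylation (median 0.17, adjusted p = 0.00266) and interferon (-0.22, 0.0487) had adjusted p = 0.561 and 0.167 with an estimated correlation. The interferon call ended without any 1 oviduct array or micromanipulation control replicate 1 or 3 (0.0866), and with each of no background correction (0.128), scaling to the 75th percentile (0.0569) and an offset of 50 (0.0816).

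The micromanipulation control and ISM1/ISM2 differed in many genes. Amino acid response and primitive endoderm genes were higher in the control. *Slc7a3* and *Nupr1* were at least 49.7-fold and at least 30.0-fold higher in the control, *Chac1* rose by 4.94 log2, *Vegfa*, the vascular growth factor, by 4.35 (2.31 on another probe), *Lama1* by 4.02, *Elf5* by 3.24, *Grb10* by 2.32, *Aqp8* by 2.27, *Sox17* by 1.72 and *Igf2* by 1.34, and *Srgn* was at least 5.94-fold higher (0.51 log2 on another probe). *Oasl2* and *Bhmt2* were at least 10.5-fold and at least 10.8-fold lower, and *Tex19.2* changed by -3.91, *Actn2*, detected on 1 of 3 control arrays, by -3.75 (-3.47 at the floor), *Ebp* by -2.52 and *Cdkn1c* by -2.45, while *Tm7sf2* was at least 1.64-fold lower. *Mest* fell by 1.35 (limma adjusted p = 0.0343; 0.126 without ISM1/ISM2 replicate 3, and ended without ISM1/ISM2 replicate 1 or any 1 control array). A total of 1455 units passed, 668 higher and 787 lower, 913 of them by at least 2-fold, with 2581 at an unadjusted p under 0.05. The count became 965 and 925 without micromanipulation control replicates 2 and 3, and 286 with the control arrays averaged to 1 sample. The amino acid response had 29 higher and 0 lower (30 and 0 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 2.14e-24; 0.0412 with an estimated correlation). Primitive endoderm had 13 higher and 0 lower (the same adjusted over the list alone), with a median of 1.78 (adjusted p = 2.4e-14; 0.00035 with an estimated correlation). Trophectoderm (median 0.56, adjusted p = 5.1e-07) and the unfolded protein response (0.33, 0.00986) were higher, with an adjusted p = 0.134 each with an estimated correlation. Cholesterol (-0.91, 2.63e-05), NRF2 targets (-0.51, 0.000127), 2-cell transcripts (-0.88, 0.0106), lysosome (-0.42, 0.0124) and interferon (-0.53, 0.0336) were lower, with adjusted p = 0.134, 0.134, 0.388, 0.12 and 0.134 with an estimated correlation. The 2-cell call ended without ISM1/ISM2 replicate 3 (0.32), where the median was -0.17, and the interferon call without oviduct replicate 3 (0.0641) or when undetected probes were kept (0.172).

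The micromanipulation control and KSOM(aa) could not be separated gene by gene. Between them 0 units passed in limma, the smallest adjusted p being 0.833, and 426 had an unadjusted p under 0.05. Without KSOM(aa) replicate 1, 123 units passed, 98 higher and 25 lower. *Rnf144b* and *Rab25*, dark in KSOM(aa), were at least 1.22-fold and at least 1.53-fold higher in the control and *Ccdc50* was higher by 1.03 log2. *Bhmt* and *Reep1* were lower by 1.47 and 0.82 and *Golt1b*, dark in the control, at least 1.43-fold lower, none passing. The amino acid response list had a median of 0.22 with 0 genes passing (camera adjusted p = 0.0295; adjusted p = 0.785 with an estimated correlation). Without KSOM(aa) replicate 1 that median was -0.01 (adjusted p = 0.998), and the call also ended without micromanipulation control replicate 3.

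**Figure D4:**
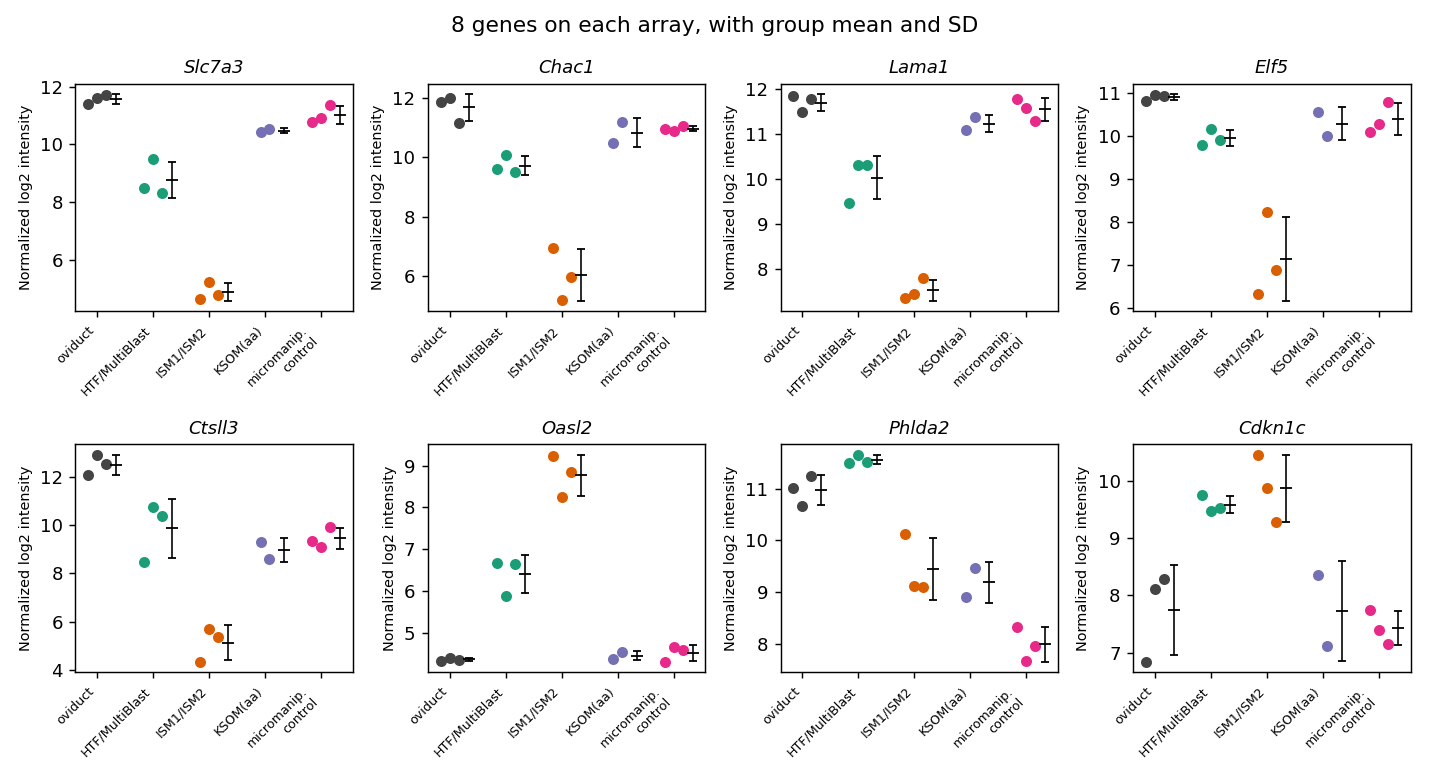
Points give the normalized log2 intensity of 8 genes on each array by group, with bars for the group mean and SD. *Slc7a3* falls from 11.58 in oviduct to 8.77 in HTF/MultiBlast and to background in ISM1/ISM2, where no array detected it, and *Phlda2* from 11.56 in HTF/MultiBlast to 7.98 in the micromanipulation control.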

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

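The fits with oviduct replicate 2 alone and with the control arrays averaged were chosen after the data were seen, and the other alternatives before. Of 248 called pairs of a named gene and a comparison, 248 kept their direction under the alternatives run and 142 also kept their call under each of them. A further 129 pairs were not called. No scaling moved the median of all units by over 0.1 log2. No fold beyond the stated bound can be given for *Slc7a3*, *Oasl2* or *Msx1* where a group was not detected. Replicate numbers do not pair the samples across groups: of 26 pairs with the same number, 8 correlated above 0.1 in their deviations, over a range of -0.358 to 0.427, and 6 of 14 samples correlated best with a sample of their own number. A slide block was not run, since the headers give no slide. Where an array left out leaves KSOM(aa) with 1 array, or oviduct is replicate 2 alone, the lone sample is assumed to vary like the other groups. Counts that stayed within 1.5 times their value are not repeated, and the cause was not tested unless stated.

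With camera's estimated correlation, 17 list tests passed in place of 76. Of the 76 called list medians, 33 moved by over 1.5 times with no background correction, 34 with no filter (1 turned) and 19 after scaling to the 75th percentile, which ended 2, 9 and 11 calls. The authors' values gave 3 units for KSOM(aa) against oviduct (1 higher, 2 lower), 15 for the micromanipulation control against oviduct, 12 for HTF/MultiBlast against KSOM(aa) and 2 shared between KSOM(aa) and the control. No background correction gave 34 for KSOM(aa) against oviduct. Scaling to the 75th percentile gave 10 for KSOM(aa) against oviduct (40.0% higher in place of 22.7%), 12 for HTF/MultiBlast against KSOM(aa) and 7 shared between KSOM(aa) and the control.

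No filter, which adds undetected probes to the adjustment, gave 350 for HTF/MultiBlast, 1 for KSOM(aa) and 24 for the control against oviduct, 14 for HTF/MultiBlast against KSOM(aa), 283 shared between HTF/MultiBlast and ISM1/ISM2 and 1 shared between KSOM(aa) and the control. Detection on all arrays, which removes genes dark in a group, gave 338 for HTF/MultiBlast, 20 for the control and 774 for the culture mean against oviduct, 2 for HTF/MultiBlast against KSOM(aa), and 263 and 8 shared.

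A fit with only the groups of a comparison leaves fewer residual degrees of freedom and takes the spread of those groups alone. Counts against oviduct were then 259 for HTF/MultiBlast, 1456 for ISM1/ISM2, 0 for KSOM(aa) (limma; 397 at an unadjusted p under 0.05), 3 for the control and 734 for the culture mean. HTF/MultiBlast against KSOM(aa) gave 0 (721 unadjusted), ISM1/ISM2 against KSOM(aa) 263, the control against HTF/MultiBlast 804 and the control against ISM1/ISM2 2277. Array weights gave 993 for HTF/MultiBlast, 1 for KSOM(aa) and 490 for the control against oviduct (54.3% higher), 1561 for HTF/MultiBlast against ISM1/ISM2, 1 for HTF/MultiBlast and 347 for ISM1/ISM2 against KSOM(aa), 1409 and 2828 for the control against HTF/MultiBlast and ISM1/ISM2, and 3014 in the F test. A replicate block gave 5 for KSOM(aa) against oviduct and 5 shared between KSOM(aa) and the control.

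An adjusted p under 0.01, a stricter threshold by construction, gave 151, 1177, 4 and 3 for HTF/MultiBlast, ISM1/ISM2, KSOM(aa) and the control against oviduct and 414 for the culture mean. It gave 233 for HTF/MultiBlast against ISM1/ISM2, 7 and 400 for HTF/MultiBlast and ISM1/ISM2 against KSOM(aa), 55 and 770 for the control against HTF/MultiBlast and ISM1/ISM2, 706 in the F test, and 132 and 1 shared. Oviduct replicate 2 alone gave 105, 1170, 6 and 2 against oviduct for the same groups and 238 for the culture mean. The control arrays averaged to 1 sample, which leaves fewer samples, gave 0 units against KSOM(aa) (limma; 69 unadjusted), and 790 in the F test, and ended 31 of 47 named calls with the control.

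Leaving out each array in turn gave ranges of 175 to 824 for HTF/MultiBlast, 1532 to 2576 for ISM1/ISM2, 6 to 286 for KSOM(aa), 1 to 176 for the control and 689 to 1881 for the culture mean against oviduct. The ranges were 279 to 797 for HTF/MultiBlast against ISM1/ISM2, 3 to 167 and 598 to 1260 for HTF/MultiBlast and ISM1/ISM2 against KSOM(aa), 45 to 300, 925 to 1738 and 0 to 123 for the control against HTF/MultiBlast, ISM1/ISM2 and KSOM(aa), and 979 to 2321 in the F test. Shared calls ranged from 158 to 656 for HTF/MultiBlast and ISM1/ISM2 and from 0 to 81 for KSOM(aa) and the control. The share of distance between groups ranged from 56.1% to 65.1%. The amino acid response median of the control against KSOM(aa), 0.22, turned to -0.01 without KSOM(aa) replicate 1 and ranged up to 0.37.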

Other observations

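The splits of the arrays were planned, except that with the control arrays averaged, and the tests of chromosomes, the amino acid response, the 2-cell transcripts and the *Kcnq1* cluster were chosen after the results were seen. The genes named in the next paragraph were also chosen after their values were seen, except those already named for the same comparison.

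In ISM1/ISM2 against oviduct, genes of some lists went both ways. Of 18 hypoxia genes, 6 were lower and 3 higher (6 and 4 adjusted over the list alone; median -0.19, camera adjusted p = 0.233). *Vegfa* fell by 3.56 log2 (-1.27 on another probe), the stress brake on growth *Ddit4* fell by 2.70 and *Ndrg1* by 1.5, while the mitophagy receptor *Bnip3l* rose by 1.01 (limma adjusted p = 0.0148; 0.0663 without ISM1/ISM2 replicate 1, and ended without oviduct replicate 1). Among osmolyte transporters (median -0.34, 2 higher and 5 lower, adjusted p = 0.113), *Slc38a2*, which imports neutral amino acids, fell by 3.99 (-3.96 and -0.25 on other probes), the glycine carrier *Slc6a9* fell by 3.47 and the glycerol channel *Aqp3* fell by 1.93, while the betaine carrier *Slc6a12* was at least 3.57-fold higher. *Bhmt* and *Bhmt2* rose by 2.66 and 3.32, with *Bhmt2* detected on 1 of 3 oviduct arrays.

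Some lists were called in no comparison. Their smallest camera adjusted p was 0.169 for TCA cycle (median -0.21 in ISM1/ISM2 against oviduct), 0.169 for heat shock (-0.16 in the control against ISM1/ISM2), 0.229 for cell cycle (-0.14 in the control against HTF/MultiBlast), 0.167 for hypoxia (0.18 in HTF/MultiBlast against ISM1/ISM2), 0.132 for cell junction (0.20 in the same pair), 0.113 for implantation-related genes (-0.40 in ISM1/ISM2 against oviduct), 0.0749 for muscle and stroma (-0.36 in the control against ISM1/ISM2) and 0.641 for oviduct epithelium (0.03 in the control against HTF/MultiBlast). Of 23 oviduct epithelium genes on the array, 2 were detected on all oviduct arrays and 3 on all HTF/MultiBlast arrays. In HTF/MultiBlast against oviduct, the osmotic list had a median of 0.07 where camera's direction was down, and in the culture mean 0.01, neither called.

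Calls in 1 direction of 5 comparisons were tested for chromosomes, each adjusted over 20. Chromosome X held 22 of 285 units higher in HTF/MultiBlast than oviduct, against 9.35 by chance (odds ratio 2.6, Fisher's exact adjusted p = 0.00444). It passed neither in ISM1/ISM2 (47 of 1150 against 37.7, adjusted p = 0.443) nor the culture mean (0.24). Its median log2 difference was 0.22 in ISM1/ISM2 and 0.16 in HTF/MultiBlast. Without the 5 *Magea* genes, X held 20 of 283 against 9.11 (odds ratio 2.39, unadjusted p = 0.000855). *Xist* was among them, and the sex-linked list had a median of 0.73 there (camera adjusted p = 0.171). Embryo sex is not given, so its part was not tested. Chromosome 7 held 123 of 1150 units higher in ISM1/ISM2, against 92.5 by chance (odds ratio 1.46, adjusted p = 0.0107), and passed neither in HTF/MultiBlast (0.924) nor in the culture mean (0.758). Among units lower in the control, X and 7 did not pass against HTF/MultiBlast (0.953 each) or ISM1/ISM2 (0.368 each).

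Other splits of the same arrays tested the counts. For the culture mean against oviduct, 1 of 100 drawn splits, the real one, gave as many calls (1182, highest other 515). These splits also mix the culture groups, which differ, so chance stays open for culture against oviduct. For the F test it was 1 of 100 (1605, highest other 882). With the 3 control arrays averaged to 1 sample it was 1 of 100 (790, highest other 68), so chance can be excluded there. With 3 arrays against 3, 10 splits are too few for a share under 0.05. The real count and the highest other were 536 and 0 for HTF/MultiBlast, 2237 and 0 for ISM1/ISM2 and 37 and 1 for the control against oviduct, 618 and 0 for HTF/MultiBlast against ISM1/ISM2, and 202 and 0 and 1455 and 0 for the control against HTF/MultiBlast and ISM1/ISM2.

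Amino acid response genes were lower in ISM1/ISM2 and HTF/MultiBlast than in oviduct, by medians of -1.55 and -0.95. Oviduct arrays that stood apart are argued against for ISM1/ISM2, whose median against the micromanipulation control was -1.82 (-1.88 to -1.64 over pairs of single arrays). For HTF/MultiBlast the same test gave -0.75 (-1.16 to -0.45), which leaves that explanation open. Normalization is argued against for both, since the medians nearest 0 under the 4 other normalizations were -1.24 and -0.72. A difference in the amino acids or stress that the media gave the embryos may lie behind the pattern, but the labels do not give the composition of the media, so it stays untested. A kind of embryo, if MultiBlast names one, is open as well.

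Genes of the 2-cell stage, such as *Zscan4c* and *Tcstv1*, were high on single arrays, with list medians of 2.05 on ISM1/ISM2 replicate 3, 0.73 on oviduct replicate 3, 0.66 on HTF/MultiBlast replicate 1 and 0.38 on oviduct replicate 1, against -0.56 to -0.18 on the others. Within groups, neither dim arrays nor unfertilised oocytes can be excluded with 14 arrays. In deviations from the group means, r with log2 median intensity was -0.52 (95% interval -0.86 to 0.17, permutation p = 0.053, adjusted 0.069 over 2 relations; rho = -0.60, permutation p = 0.044; r = -0.52 without the 2 arrays farthest from their group). With the oocyte list r was -0.77, the direction opposite to oocytes (-0.94 to -0.27, permutation p = 0.069, adjusted 0.069; rho = -0.60, permutation p = 0.087; r = -0.43 without the 2 farthest). Embryos stalled early, or cells that re-entered a 2-cell-like state, might also carry these transcripts, and neither was tested.

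Imprinted genes of the *Kcnq1* cluster on chromosome 7 differed between groups. Of its 7 listed genes, 5 passed the F test: *Phlda2* (adjusted p = 2.4e-05), *Cd81* (5.23e-05), *Slc22a18* (0.000107), *Cdkn1c* (0.00165) and *Ascl2* (0.0464), but not *Nap1l4* and *Tssc4*. The cluster was picked because its genes differed, so its share is not tested against others. A change of the whole region stays open: 2 of 14 other units within 1 Mb passed (14.3%, exact 95% interval 1.78% to 42.8%; 18.5% of all units), too few to exclude a share of 35.7%, 0.5 times the cluster's 71.4%. Normalization is argued against, since 4 of the 5 passed under each of the 4 other normalizations. The genes did not move as a block: *Cd81* rose by 1.85 and 2.41 log2 in HTF/MultiBlast and ISM1/ISM2 against oviduct, while *Phlda2* was higher by 0.58 without passing in HTF/MultiBlast and fell by 1.52 in ISM1/ISM2. Altered imprint control is a candidate explanation and was not tested.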
